A study of Drosophila melanogaster with 2 samples.

How the data were processed

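Small RNA was sequenced from the dissected central nervous system (CNS) of Drosophila melanogaster at 2 stages, with 1 library per stage, each from about 100 pooled animals of an isogenic white-eyed strain. Per the labels' protocols, the larval dissection held the ventral ganglion with the optic lobes of wandering larvae of the last instar, without the eye discs. The adult dissection held the brain with the antennal lobes, 3 to 5 days after eclosion. Both libraries were made with an Illumina TruSeq small RNA kit and carried different indexes. Stage and dissection change together in this design, so they cannot be separated.

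The authors deposited read counts per annotated miRNA hairpin for each library. Per the file headers, reads were trimmed, and each count is divided into the 5' mature arm, the 3' mature arm and other reads of the hairpin, with separate columns for reads equal to the annotated mature form and for reads that fit 1 hairpin only. A read that fitted several hairpins was counted in each of them, as the difference between the deposited total and unique counts shows. CASAVA 1.8 and the genome build dm3 are named in the submitters' processing notes. The aligner, the counting program and the miRNA annotation release are not given in the sources used here. The authors' deposited table of the comparison holds RPM values (reads per 1000000 reads of the table), a signed fold change, and the p-value and Bonferroni p-value of Kal's Z-test, per the file headers. The authors also deposited a list of candidate hairpins per library, with a score and a count of mature reads for each. The predictor behind the score is not given in the sources used here.

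The tables list 174 hairpins in all. The larval library held 822500 hairpin reads and the adult library 1665159, so 1 read stood for 1.22 RPM in the larval and 0.601 in the adult library. A count of 0 allows up to 3 reads, or 3.65 and 1.80 RPM. The intervals and these limits cover the counting error of reads only. With 1 library per stage they leave out the spread between animals, dissections and library preparations. The kit has no molecular identifiers, so reads copied from a single molecule were not told apart, and the intervals may be too narrow as counting error of molecules.

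Levels were computed as RPM of the hairpin reads of a library. A hairpin was compared if it had at least 20 reads over both libraries and at least 10 RPM in either. It was called higher in a library when the ratio was at least 2 and its exact conditional binomial 95% interval (Clopper-Pearson) excluded 1. With 1 library per stage there is no replicate check, no p-value was computed, and each call compares these libraries, not the stages in general. Log2 ratios are adult over larval with 0.5 reads added to each count. A ratio against a count of 0 is given as a lower bound against 3 reads, which leaves out the counting error of the other count. List medians were set against 10000 random lists of the same size matched on mean level in 5 bins, and given as a percentile that describes these libraries. The random lists drew hairpins singly, so the percentiles take no account of members that lie in a shared transcript. Intervals of the list medians come from 1000 Poisson redraws of the counts.

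Arm usage was the 5' share of mature reads in hairpins with at least 20 mature reads in each library and reads on both arms. A share was called different when it moved by at least 10 percentage points and the exact binomial intervals did not overlap. Candidates were called shared when they lay on the same strand and overlapped by at least 50% of the shorter one. Cluster members were compared by the absolute difference of their log2 ratios, against 10000 random sets of pairs, each random pair drawn independently. Copies of a single miRNA were not paired with each other.

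The hairpins named were fixed by a rule before the data were examined. They are the 10 largest log2 ratios in each direction that met the call, with a hairpin at 0 in a library ranked by its bound, the 10 most abundant hairpins of each library, and the members of 24 lists of miRNAs that passed the floor. The lists were the let-7 complex, the Hox complexes, the miR-309 cluster, the miR-2 seed family, neuronal, memory and ageing, progenitor and growth, sensory organ, circadian, fat and metabolism, muscle, testis, ovary and germline, mirtrons, and the clusters of miR-959, miR-277, miR-310, miR-12, miR-275, miR-279, miR-9b, miR-13, miR-11 and miR-318. Several lists share members. Names with other reasons for their choice are marked as chosen after their values were seen.

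Positions of annotated hairpins were looked up by name in the Ensembl release 115 annotation of assembly BDGP6, which held 172 of the 174 names, and were not combined with any dm3 position. Candidate positions are given in dm3 as the deposited lists give them.

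Alternatives were TMM factors from edgeR 4.0.16, size factors from DESeq2 1.42.0, a total without the 10 most abundant hairpins of either library, other floors, other ratio thresholds, summed copies and other reads added. Unique reads, mature reads without the other reads of a hairpin, exact reads for arm usage, lists and clusters with 1 copy per miRNA, and thinning of the adult library to the larval total were added after the data had been seen. The rule was tested on 100 simulated pairs of libraries with Poisson counts, the 174 hairpins' mean levels and 40 hairpins changed in each. Of those past the floor, 93.5% of the hairpins changed 2.5-fold and 99.1% of those changed 4-fold were recovered, 0.441% of unchanged hairpins were called, and 95.3% of the intervals held the true ratio. No spread between libraries was simulated and the interval is derived for such counts. These rates check the computation and are not error rates for a comparison of stages. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3.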

Results

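miRNA reads were counted in 1 larval and 1 adult CNS library of Drosophila melanogaster, with 822500 reads over 139 hairpins in the larval and 1665159 reads over 169 hairpins in the adult library. Of the 174 hairpins in all, 134 were listed in both libraries. After the floor on low counts 114 hairpins were compared. Their levels had a Spearman correlation of 0.779 between the libraries, across hairpins, which are not independent replicates. There were no replicates at either stage, and the intervals below cover counting error only.

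Few miRNAs supplied most reads at both stages. miR-184 was the most abundant hairpin of each library, with 22.2% of larval reads (95% interval 22.1 to 22.3) and 12.8% of adult reads (12.7 to 12.8). miR-276a, a miRNA of olfactory memory, held between 19.9% and 20.1% of larval reads and 12.1% of adult reads, and miR-276b, nearly identical to it in its 3' arm, held 10.7% and 12.2%. The deposited counts assign every 3' read of this pair to a single hairpin, and the split between them is uncertain. bantam, a promoter of tissue growth, held 3.76% and 5.19%. The 10 most abundant hairpins took 82.8% of larval reads (82.7 to 82.9) and 75.9% of adult reads (75.9 to 76.0), and 6 hairpins were among the 10 of both libraries, the others being miR-317 and miR-8. The libraries parted in the rest of these lists: miR-315, miR-92b, miR-10 and miR-11 were among the larval 10, and miR-957, miR-14, miR-999 and miR-277 among the adult 10. miR-315 held 11.9% of reads in the larval library and 1.65% in the adult one, while miR-957 stood at 1.30% and 11.1% and miR-14 at 0.874% and 7.99%.

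The design asks which miRNAs of the CNS differ in level between the larva and the adult. In the adult library miR-274 was 436-fold higher (95% interval 170 to 1601; 4 larval and 3531 adult reads), miR-210, a miRNA of photoreceptors, 176-fold (142 to 222), and miR-277, a regulator of branched-chain amino acid breakdown, 78.3-fold (69.3 to 88.9). miR-193 had 281 adult reads and 0 larval reads, and was thus 46.3-fold higher against the 3 reads that a count of 0 allows. With its 278 mature adult reads alone the lower end of the exact interval was 37.6. miR-133 was 25.1-fold higher (22.8 to 27.7), miR-285 26.1-fold (15.5 to 48.0), let-7 16.9-fold (15.4 to 18.6) and miR-125 14.5-fold, with 173 larval and 5078 adult reads. miR-969 and miR-954 each had 1 larval read and ratios of 79.5 (14.1 to 3160) and 30.1 (5.21 to 1209), which fixes their direction and little of their size. Among the abundant miRNAs, miR-957 was 8.55-fold (8.39 to 8.72), miR-14 9.14-fold (8.93 to 9.36) and miR-999 3.78-fold (3.69 to 3.86) higher in the adult library.

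In the larval library miR-92b was 186-fold higher (166 to 209; 28009 larval and 305 adult reads) and its relative miR-92a 113-fold (81.2 to 163). Both have been tied to neural stem cells. miR-iab-4, encoded in the bithorax complex, was 140-fold higher, with 138 larval and 2 adult reads and an interval of 37.9 to 1165. miR-275 was 27.2-fold (24.6 to 30.2), miR-282 15.9-fold (13.2 to 19.2), miR-9c 14.7-fold (13.9 to 15.6), and miR-9b 8.42-fold (7.35 to 9.67) higher, and for the abundant miR-315 the interval of the ratio was 7.11 to 7.30. The copies miR-6-1, miR-6-2 and miR-6-3 had 21, 19 and 20 larval reads and 3 adult reads each. They share reads, so they amount to a single uncertain measurement.

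By the rule of size and counting error, 46 hairpins were higher in the adult library, 28 were higher in the larval library and 40 met neither. The ratio, or its lower bound for a count of 0, was at least 10 for 11 of the adult hairpins and 9 of the larval ones, the 3 copies of miR-6 included. With copies summed the calls were 46 and 26. The split leaned on the scaling. With the total taken without the 10 most abundant hairpins of either library, all log2 ratios dropped by 0.52, the median of the compared hairpins went from 0.47 to -0.05, and 40 hairpins were higher in the adult and 41 in the larval library, so that 49.4% of calls pointed to the adult library in place of 62.2%.

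**Figure D1:**
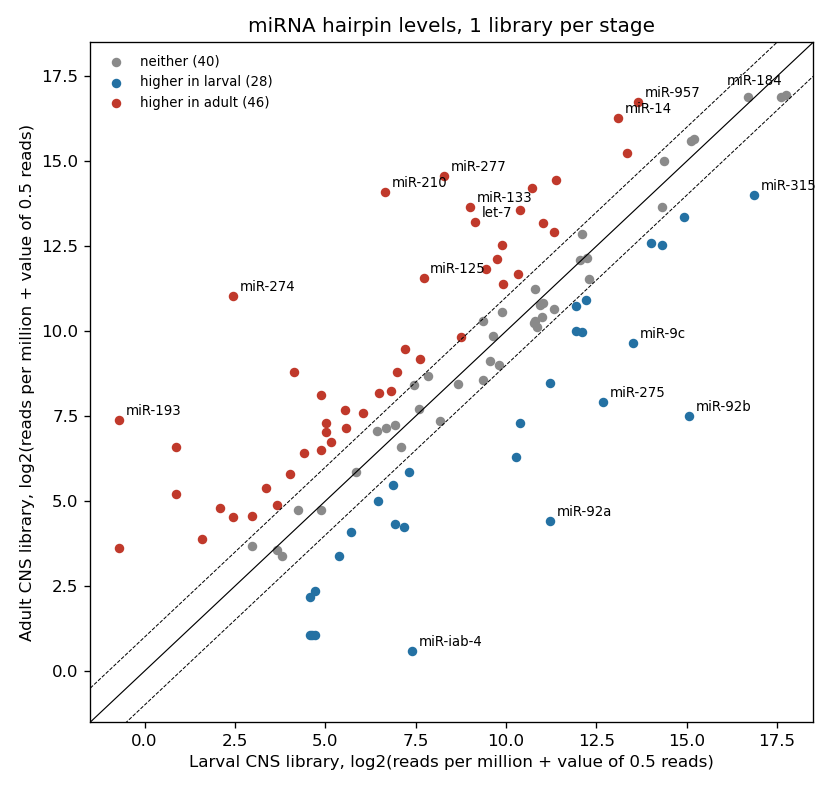
Each point is a miRNA hairpin past the floor, with its log2 level in RPM in the larval library on the x axis and in the adult library on the y axis, 0.5 reads added to each count. The solid line marks equal levels and the dashed lines a 2-fold ratio; 46 hairpins higher in the adult library lie above, with miR-274, miR-210 and miR-277 farthest from the line among those with larval reads, and 28 higher in the larval library lie below, with miR-92b, miR-iab-4 and miR-92a farthest.

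Only 2 hairpins had at least 20 reads in a single library and 0 in the other, both in the adult one. miR-193 had 281 reads and miR-263b, a miRNA that protects sensory bristles, had 20, which puts it 3.29-fold higher against 3 reads. With its 18 mature reads alone miR-263b was under the floor, and the lower end of the exact interval was 2.21. Of the hairpins listed in a single library, 35 were adult and 5 larval, and none of the larval ones had more than 3 reads. For the rest, a difference was not detectable at this depth under this rule.

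The annotation of assembly BDGP6 places the hairpins of the largest ratios in different settings. miR-92a (3R, 25646506 to 25646600, plus strand) lies in an intron of jigr1, and miR-92b (3R, 25651398 to 25651497) overlaps an exon of the same gene. miR-9c (2L, 16697924 to 16698015) and miR-9b (2L, 16698744 to 16698834) lie in introns of grp. let-7 (2L, 18472034 to 18472111) and miR-125 (2L, 18472315 to 18472424) lie in an exon of the long noncoding RNA of the let-7 complex. miR-iab-4 (3R, 16856275 to 16856342) lies in an exon of the iab4 noncoding RNA. miR-969 (X, 18124357 to 18124450) and miR-210 (X, 18128219 to 18128318) are neighbours on the plus strand with no host gene on their own strand, and miR-274 (3L, 11656918 to 11657017) also has none on its strand.

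The let-7 complex, which ecdysone switches on at metamorphosis, was higher in the adult library in all 3 members, with a median log2 ratio of 3.85 (interval 3.65 to 4.08) at the 99.3rd percentile of random lists. miR-100 had the smallest ratio, 4.42-fold. The list of progenitor and growth miRNAs had 7 of 8 members higher in the larval library and a median of -2.61 (interval -2.72 to -2.51), at the 0.07th percentile. The exception was bantam, with a log2 ratio of 0.47 that turned to -0.05 with the total without the 10 most abundant hairpins. This list holds all 4 members of the miR-9b cluster, and miR-92a and miR-92b lie in the same gene. Its members are thus not independent, and its percentile may be too extreme. miR-9a, which limits sensory organ precursors, was 4.45-fold higher in the larval library. The miR-309 cluster, known for the clearance of maternal transcripts in the early embryo, was also higher in the larval library in miR-286, miR-5 and the copies of miR-6. Its median over all 5 hairpins was -3.50 (0.285th percentile), and with miR-6 counted once it was -2.93 over 3 members, at the 0.635th percentile. Counts were low, and miR-286 had the most with 118 larval and 31 adult reads.

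The miRNAs of the Hox complexes were higher in the larval library in all 3 compared members, with a median of -1.56 at the 6.06th percentile. miR-10 was 2.96-fold and miR-993 2.43-fold higher beside miR-iab-4. miR-iab-8 had 13 larval reads and 1 adult read, under the floor. The larval dissection held the ventral ganglion, where these complexes pattern the segments, and the adult dissection did not. Stage and dissection cannot be told apart here as the source of the difference, and miR-10 still had 17448 adult reads.

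Neuronal miRNAs went both ways. Of 7, miR-219 (9.59-fold), miR-932 (5.21-fold) and miR-137 (2.72-fold) were higher in the adult library and miR-315 in the larval one. miR-190 was higher in the larval library with mature reads alone, 2.40-fold, and met neither call with all hairpin reads. miR-124, a conserved miRNA of neurons, had 2564 RPM (reads per 1000000 hairpin reads) in the larval and 1603 in the adult library, a log2 ratio of -0.68. The median was 0.75 at the 66.4th percentile, and without the 10 most abundant hairpins in the total 2 were higher in the adult and 3 in the larval library. In the memory and ageing list miR-34, which affects the ageing of the brain, was 8.32-fold higher in the adult library (7.97 to 8.69) and the other 5 met neither call. With that total, 1 of these, miR-276a, was higher in the larval library, and the median of 0.41, at the 42.5th percentile, turned to -0.11.

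The sensory organ list had miR-210 and miR-263b higher in the adult library and miR-263a higher in the larval one, 2.28-fold, with a median of -0.19 at the 34.6th percentile. The circadian list had 3 adult and 2 larval members among 9, with a median of -0.58 at the 16.0th percentile. The counts of members higher in the larval library went to 3 and 5 in these lists with the total without the 10 most abundant hairpins. miR-7, a miRNA of photoreceptor development, had a log2 ratio of 0.21, which turned negative with that total, as every ratio drops by 0.52. In the fat and metabolism list miR-277, miR-14 and miR-278 (5.22-fold) were higher in the adult library, miR-8 and miR-33 met neither call, and the median was 2.38 at the 90.8th percentile. Of these, miR-277, miR-14, miR-278 and miR-8 were also taken as markers of fat body next to the CNS, but whether they are specific to it was not tested. Of the miR-959 cluster, another set of fat body markers, 4 hairpins were listed, none past the floor and none with more than 3 adult reads.

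Among markers of other neighbouring tissues, those of muscle, testis and ovary were low. miR-210, a miRNA of photoreceptors, was not, with 29284 adult reads, and carry-over of eye tissue into the adult dissection was not tested. miR-1, the muscle miRNA, had 47.4 RPM in the larval and 141 in the adult library, 2.98-fold higher in the adult (2.11 to 4.29). Of the testis cluster 6 hairpins were listed and none passed the floor, with at most 11 reads. The ovary and germline list had miR-311 and miR-312 higher in the larval library, with 21 and 19 reads there, and miR-318 higher in the adult library with 38 reads, for a median of -2.36 at the 8.62nd percentile, or the 2.34th with 1 copy per miRNA. Mirtrons, which are made by splicing in place of Drosha, had 6 of 10 members higher in the adult library and miR-1008 higher in the larval one, with a median of 1.38 at the 82.4th percentile. With the total without the 10 most abundant hairpins miR-1005 lost its call, which left 5 higher in the adult library. With mature reads alone miR-1008 had 2 larval and 12 adult reads and was under the floor, and miR-1004 was 2.23-fold higher in the adult library (1.71 to 2.93). The miR-2 seed family had 1 adult and 3 larval calls among 13 hairpins, several of which share reads, and a median of -0.23 at the 20.3rd percentile. Its larval calls were the copies of miR-6, and with the total without the 10 most abundant hairpins miR-11, miR-13b-1 and miR-13b-2 joined them, for 6. Its adult call, miR-2c (2.12-fold), was lost with that total and with DESeq2 size factors. It rested on other reads of the hairpin, counted in neither mature arm: with mature reads alone, 177 larval and 388 adult, the ratio was 1.10 (0.920 to 1.32). Among the other list members, miR-308 was then 2.47-fold higher in the larval library, with 31 and 25 mature reads.

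**Figure D2:**
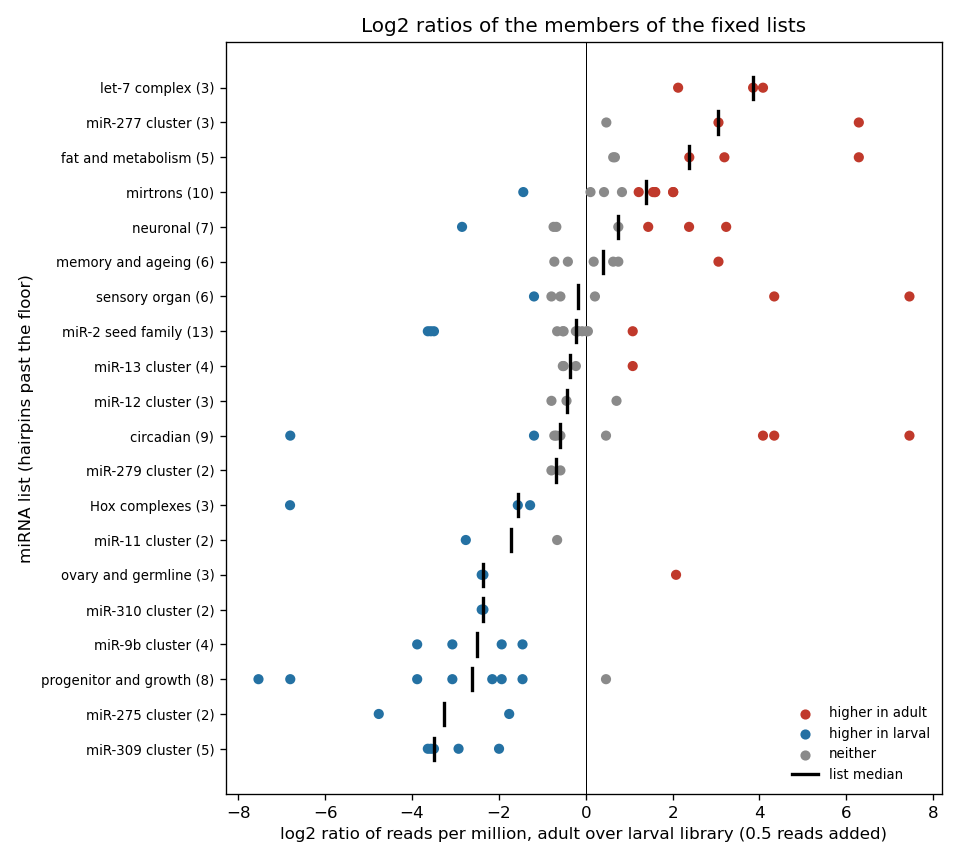
Each point is a hairpin of a fixed list with at least 2 hairpins past the floor, placed by its log2 ratio of adult over larval RPM, and the bars are list medians. Copies of a miRNA are separate points. The let-7 complex has the highest median, 3.85, and the miR-309 and miR-275 clusters lie on the larval side; lists with calls on both sides include the neuronal, sensory organ and circadian ones.

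miRNAs listed together as genomic clusters had closer ratios than most random sets of pairs, with exceptions of large size. Over 31 pairs the median absolute difference of log2 ratios was 1.5, at the 2.18th percentile of random sets of pairs, whose median was 2.40. These pairs hold copies by name, among them miR-13b-2, which lies on X (9091230 to 9091299, in an intron of CCT2) and not with the miR-13 cluster on 3R. With 1 copy per miRNA, all on a shared chromosome, 25 pairs had the same median, at the 3.53rd percentile. Over 35 pairs taken from annotated positions within 10 kb it was 1.31, at the 0.43rd percentile. This set still held copies that share reads, such as those of miR-6, and was not reduced to 1 copy per miRNA. Pairs within a cluster share members, which the independently drawn random pairs do not reproduce. These percentiles may therefore be too extreme. All 4 members of the miR-9b cluster, which are also in the progenitor and growth list, were higher in the larval library, at a median of -2.50 and the 1.8th percentile. Both members of the miR-275 cluster were too (median -3.26, 3.15th percentile), though miR-275 and miR-305 differed by 3.00. In the miR-277 cluster (median 3.06, 76.0th percentile) the log2 ratios were 6.29 for miR-277, 3.06 for miR-34 and 0.47 for miR-317, and the last turned to -0.05 with the total without the 10 most abundant hairpins. The miR-310 cluster had a median of -2.38 (6.59th percentile, or 2.04th with 1 copy per miRNA), the miR-11 cluster -1.71 (15.4th), the miR-279 cluster -0.69 (26.1th), the miR-12 cluster -0.44 (33.3th) and the miR-13 cluster -0.37 (31.0th). Without miR-13b-2 the last was -0.23, at the 47.4th percentile. With the total without the 10 most abundant hairpins, members higher in the larval library went from 1 to 2 in the miR-11 cluster and from 0 to 2, 1 and 2 in the miR-279, miR-12 and miR-13 clusters. The miR-318 cluster had a single hairpin past the floor, miR-318, at a log2 ratio of 2.08.

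The arm from which reads came differed in 17 of 76 hairpins, toward the 5' arm in the adult library in 7 and toward the 3' arm in 10. The 5' share of miR-124 was 67.9% in the larval library (65.8 to 70.0) and 18.2% in the adult one (16.5 to 19.9). miR-305 went the other way, from 30.3% (29.6 to 31.0) to 81.6% (80.8 to 82.4), miR-34 from 25.0% (23.0 to 27.2) to 50.3% (49.8 to 50.9), and miR-125 from 53.3% (45.4 to 61.0) to 91.4% (90.6 to 92.2). miR-278 had 49.4% (45.7 to 53.2) in the larval library and 10.3% to 11.8% (the interval) in the adult one, and miR-11 had 29.4% (28.7 to 30.1) and 13.7% (13.3 to 14.2). The majority arm changed in 5 hairpins, miR-124, miR-2c, miR-305, miR-34 and miR-965, of which miR-965 was chosen after its values were seen. Among reads equal to the annotated form the majority arm changed in 0 of the 4 of these with reads on both arms. It did change in other hairpins, such as miR-932 with a 5' share of 15.5% (9.97 to 22.5) and 68.0% (65.2 to 70.7) and miR-278 with 59.8% and 20.9%. With all mature reads the majority of miR-932 was on the 5' arm in both libraries, 78.8% and 93.0%. Only 4.88% of its larval and 14.4% of its adult 5' reads were exact, against 99.2% and 90.8% of its 3' reads. The change of miR-932 among exact reads thus leaves out most of its 5' reads. For miR-305 the exact reads were 0.821% and 3.56% on the 5' arm, no difference by the rule, while for miR-124 they were 92.6% (91.0 to 94.0) and 58.5% (54.2 to 62.7). Only 1.43% of the larval and 0.254% of the adult 5' reads of miR-305 were exact. Exact reads therefore cannot decide whether its change with all reads holds.

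**Figure D3:**
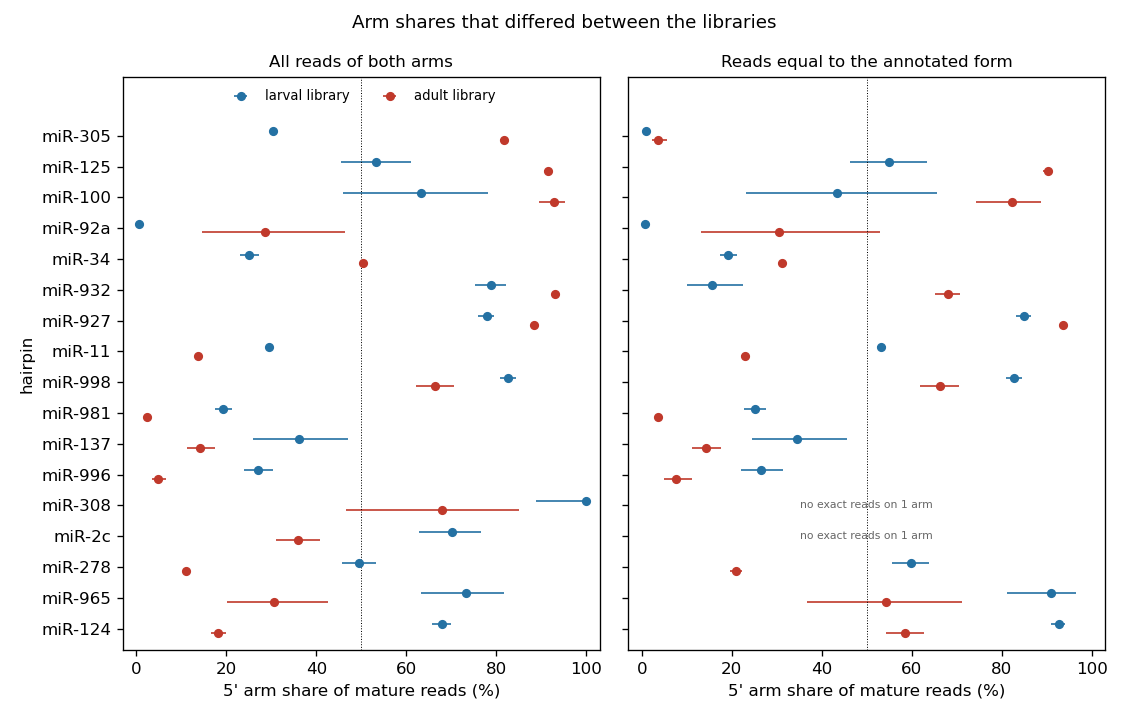
The 5' arm share of mature reads, in percent, of the 17 hairpins whose share differed, in the larval and the adult library, with exact binomial 95% intervals as bars; all mature reads on the left, reads equal to the annotated form on the right. miR-124 goes from 67.9% to 18.2% and miR-305 from 30.3% to 81.6% with all reads. The difference of miR-305 is absent by the rule with exact reads, but only 1.43% of its larval and 0.254% of its adult 5' reads were exact.

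Reads equal to the annotated mature form made up 77.2% of mature reads in the larval library (77.1 to 77.3) and 76.5% in the adult library (76.4 to 76.5). The abundant miRNAs ranged widely. miR-276b had 99.3% exact reads in the larval and 97.9% in the adult library, miR-184 94.4% and 86.7%, bantam 75.4% and 70.0%, miR-14 56.1% and 50.8%, and miR-315 8.26% and 11.7%. Without the 14 most abundant hairpins the exact share was 63.4% (63.2 to 63.7) in the larval and 50.3% (50.1 to 50.5) in the adult library. Over all hairpins the 5' arms went the other way, from 34.7% (34.5 to 34.9) to 48.9% (48.7 to 49.2), and the 3' arms from 89.3% (89.2 to 89.4) to 80.6% (80.6 to 80.7). These pooled shares also depend on which hairpins were abundant in each library. The 5' arm of miR-315, with 7.95% exact reads in the larval and 11.1% in the adult library, dominated the larval 5' reads. It supplied 97076 of the 178183 larval 5' reads and 27115 of the 209301 adult ones. The rise of the pooled 5' share therefore does not show that 5' arms in general held more exact reads in the adult library.

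The authors listed 68 candidate hairpins in the larval library and 62 in the adult library, which came to 43 and 32 distinct mature sequences, since a sequence could be listed at up to 10 and 15 places. The libraries shared 25 candidates on the same strand. The authors' score was above 0 for 9 larval and 10 adult candidates, which came to 6 and 5 distinct mature sequences. The candidate with the most reads, at dm3 2L 14530889 to 14530975 on the minus strand, had 10934 larval and 507 adult mature reads, 43.7-fold higher in the larval library relative to its hairpin reads (39.9 to 47.8). Its score was -4.89 in both libraries, and it carried a tRNA promoter motif of the kind described below. What the genome annotation holds at these dm3 positions was not analysed here.

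The authors' deposited table gave a fold change for 134 hairpins, which had the same direction as the recomputed ratio in every case, with 0 differences and a Pearson correlation of 1 across hairpins, because it is the ratio of the same RPM values. The authors' deposited table lists 94 hairpins with a Bonferroni p-value under 0.05, of which 51 were higher in the adult and 43 in the larval library. Of these, 25 differed by less than 2-fold in the authors' deposited table. Of the calls made here, 6 had no Bonferroni p-value under 0.05 in the authors' deposited table. That Z-test compares the reads of these libraries, not the stages.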

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

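Of the tests in this part, the one of a bias toward one arm, those with exact reads and the values of thinned, shared and mature reads were chosen after the data had been seen. The 3 hairpins below were picked because over 50% of their reads in each library were other reads, counted in neither mature arm. They were found among 66 hairpins with at least 100 reads in each library. These other reads enter the hairpin totals but no comparison of their own, and where they lie on the hairpin was not analysed here. For miR-317 such reads were 53.8% of the larval (53.2 to 54.3) and 56.4% of the adult reads (56.0 to 56.7). The mirtron miR-1004 had 63.2% (55.9 to 70.0) and 54.9% (51.1 to 58.6), and miR-2c 50.4% (45.1 to 55.7) and 74.7% (72.4 to 76.8). They carried the call of miR-2c, 2.12-fold higher in the adult library with all hairpin reads and 1.10-fold (0.920 to 1.32) with mature reads alone. No control library was analysed here, and each count is far above the 3 reads that a count of 0 allows.

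More hairpins were higher in the adult than in the larval library, 46 against 28. The larger adult library does not account for it: thinned to the larval total, it gave a median of 43 hairpins higher in the adult library over 100 draws (41 to 45), against 28 in the larval one. The scaling stays open as a cause. TMM factors gave 46 and 28, which argues against it, and the total without the 10 most abundant hairpins gave 40 and 41, which ends the excess. The value set in advance was the TMM one, and it was not read as decisive because the total without the abundant hairpins removes the suspected source directly. A difference between the stages, or between the dissections, may underlie the excess and was not tested.

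Arm shares differed in 17 hairpins, and a bias of a whole library toward one arm is argued against as the cause of all of them, since 10 moved toward the 3' arm in the adult library and 7 toward the 5' arm, with intervals that did not overlap. Reads shared with other hairpins are too, since by the deposited unique counts the shared mature reads were 0% in each of the 17. Variant reads are argued against as the only cause for 13 of the 15 hairpins with exact reads on both arms (86.7%), which kept the difference with exact reads, among them miR-124, miR-34 and miR-125. Keeping it asks only that 10 percentage points remain, so variant reads may still carry part of a difference. The change of miR-34 was 25.3 points with all reads and 12.1 with exact reads, and that of miR-932 was 14.2 and 52.5. Variant reads stay open for the other 4 hairpins, as miR-2c and miR-308 could not be tested, miR-927, named after its values were seen, moved by 8.77 percentage points with exact reads, and miR-305 by 2.74. For the 13, a change of arm with stage or dissection may be a cause, a hypothesis found and tested on the same data.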

How the results depend on the processing

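No other scaling, floor or copy rule moved the 46 and 28 calls by over 1.5 times; these gave 34 to 48 adult and 20 to 41 larval hairpins. A ratio of at least 4 gave 30 and 18, since it asks for more. Requiring at least 10 or 100 reads changed the hairpins listed in a single library from 2 to 4 or 1. With 5 reads added, the median difference within clusters was 0.95, at the 0.11th percentile, as added reads by construction draw low counts together. The exact share without the 10 most abundant was 63.4% in the larval and 50.3% in the adult library. The upper part of each candidate list by reads shared 16 candidates in place of 25, as fewer entered. With the total without the 10 most abundant every log2 ratio drops by 0.52. Among the most abundant hairpins those of miR-276b, bantam and miR-317 turned to -0.34, -0.0542 and -0.0467, and the memory and ageing median turned to -0.11. List members with a positive ratio under 0.52, such as miR-7, turned as well. TMM and DESeq2 factors shifted ratios by -0.06 and -0.15. Over all other settings of the list medians 132 values lay within the counting interval, 43 outside it and 1 turned. For the hairpins named for the largest ratios or the highest abundance, without those named only as list members, these were 168, 48 and 3. The counts of differing arm shares were 12 to 21, and with unique or exact reads, chosen after the data had been seen, 19 and 17. The authors' deposited fold change gave 44 and 28. With 1 copy per miRNA, also chosen after the data had been seen, the median difference within clusters stayed at 1.5; the pool of random lists and its level bins changed, and the percentiles of the ovary and germline list and the miR-310 cluster went from 8.62 to 2.34 and from 6.59 to 2.04. Mature reads alone, likewise added, gave 45 and 29 calls, 44 and 27 of them shared with the 46 and 28; miR-2c, miR-263b and miR-1008 lost theirs. Scaling to all small RNA reads was not run, because such a total was not used here. No paired analysis was possible because each stage has 1 library. Depth limits ratios that rest on few reads, such as those of miR-969, miR-954 and miR-iab-4.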

Other observations

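The tests of the tRNA motifs in this part were chosen after the data had been seen, and so were the miRNA arms named here. The share of reads equal to the annotated form differed between the libraries in some arms; ends, mismatches and added bases were not told apart. Of 80 arms with at least 100 reads in each library, the share of exact reads was at least 10 percentage points lower in the adult library in 22 and higher in 7, with intervals that did not overlap. Copies counted once, these were 22 and 6 of 77 arms, as miR-13b-1 and miR-13b-2 have nearly the same 3' reads. Of the 22, 8 belonged to hairpins higher in the larval library, 4 to hairpins higher in the adult library and 10 to hairpins with neither call, against 20, 25 and 35 of all 80 arms. The 3' arm of miR-278, higher in the adult library, had 65.1% and 45.5% exact reads. The 5' arm of miR-9c had 82.8% exact reads in the larval (82.0 to 83.5) and 52.3% in the adult library (49.5 to 55.0), that of miR-9b 58.8% (55.4 to 62.2) and 19.6% (14.7 to 25.5), and the 3' arm of miR-275 88.4% (87.4 to 89.3) and 51.4% (46.1 to 56.7).

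The 5' arm of let-7 went the other way, from 43.7% exact reads in the larval library (39.1 to 48.4) to 75.8% in the adult one (75.1 to 76.5). The 3' arm of miR-305 fell from 75.2% (74.4 to 76.0) to 30.5% (28.3 to 32.8), and the 5' arm of miR-34 from 69.7% (65.2 to 74.0) to 44.1% (43.3 to 44.9). miR-317 and the 3' arm of miR-11 had more exact reads in the adult library, 68.9% against 58.7% and 50.0% against 34.9%.

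A motif of the internal tRNA promoter (an A-box-like or B-box-like pattern) was carried by 12 of the 43 distinct larval candidates, with 84.6% of the reads, and by 7 of 32 adult ones, with 56.3%. Motifs by chance are argued against, since shuffled larval sequences gave 1.42 such hairpins on average. Of 17 sequences shared between the libraries, the 7 with a motif were all higher in the larval library relative to hairpin reads, by 7.04-fold to 43.7-fold with a median of 15.4-fold, and by the same rule 8 of the 10 without one were too, the 10 lying between 0.880-fold and 12.3-fold with a median of 4.59-fold. One larger share of all non-miRNA fragments in the larval library stays open: the difference of the median log2 ratios was 1.74, outside the 95% range of random relabellings (-1.42 to 1.30), but among the 9 with at least 100 larval reads, of which 2 had no motif, it was 0.40, inside that of the 36 relabellings (-1.20 to 0.82). The subset of 9 cannot decide the question, because larval reads enter the ratio itself and only 2 of its sequences lack a motif. A candidate explanation is that these hairpins are tRNA fragments more frequent in the larval library, by stage, dissection or RNA handling, which the design leaves confounded; whether they are tRNA genes was not analysed here.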
